A study of Mus musculus with 42 samples.

How the data were processed

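Gene expression was measured on Affymetrix arrays in mouse placenta (the fetal part), in decidua (the maternal part of the implantation site) and in whole placentas left undissected at embryonic day 17.0. Per the labels' protocols, placentas of Swiss Webster mice were separated by hand with forceps into both parts, each part was pooled per litter, RNA was isolated with Trizol and purified on a column, and biotin-labelled cRNA was hybridised. Per the same protocols, both undissected samples were single placentas of 1 C57BL/6 female, and a pair of the e8 samples were pooled from several litters.

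The deposited values were linear intensity values, 1 column per array, for 45101 probe sets on 42 arrays. Per the series title, the authors normalized and modeled the time course together with the undissected samples. The summarisation and normalization software was not given in the sources used here, and the linear scale was read from the values, which were positive and right-skewed with array medians of 156.7 to 190.9. The authors' array medians were close but not equal, and between 4 and 30 probe sets per array lay at or below 1. The design had allowed for either log2 or linear values, and the linear branch was used: values were changed to log2(value + 16). Every column was matched to its sample record.

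Probe sets were named through the platform annotation. Of the 45101 probe sets, 34945 had exactly 1 gene symbol, 932 had several, 9160 were unnamed here and 64 were controls. Gene identifiers of 34741 probe sets matched the RefSeq gene table, and 0 symbols needed updating. Only probe sets with 1 symbol were used, and the probe set with the highest mean over all samples stood for its gene, which left 18193 genes. Prl3b1, Gcm1, Syna, C3, Xist and Ddx3y had no such probe set and were not analysed here. Near-identical families (Prl2c, Prl3d, Psg, Ceacam, Gzm, Hba and Hbb) were treated as uncertain as to the member, since probes can bind more than 1 of them. The annotation carried no genome build, so positions are not given.

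Both technical arrays of each decidua e8.5 sample were averaged first, which left 40 biological samples in 18 groups. A linear model with 1 mean per group was fitted in limma 3.58.1 (R 4.3.3) with empirical Bayes moderation, 22 residual and 4.7 prior degrees of freedom. All samples shared this estimate of the spread, because most groups held 2 or 3. P-values were adjusted by the Benjamini-Hochberg method over all 18193 genes in each comparison, two-sided, and a gene was called at an adjusted p below 0.05. Counts at 2-fold or more (1 on the log2 scale) are given beside these. Tables and figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

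The comparisons were placenta less decidua averaged over 7 shared stages (e9.0, e10.5, e12.0, e15.0, e17.0, e19.0 and the day of birth, P0), late (e15.0, e17.0 and e19.0) less early (e9.0 and e10.5) in each tissue, the difference between these changes, P0 less e19.0, undissected less each dissected tissue at e17.0, and each step between adjacent stages. A gene counted as outside both tissues when it was called in the same direction against each. These comparisons, the gene lists, the rule for naming genes and the first set of alternative settings were chosen before the data were examined.

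The 29 gene lists were the prolactin family, the PSG and CEACAM family, placental cathepsins, trophoblast stem and progenitor cells, spongiotrophoblast and glycogen cells, trophoblast giant cells, labyrinth and syncytiotrophoblast, nutrient transporters, imprinted genes, decidual stroma, uterine natural killer cells, macrophages and leukocytes, neutrophils and acute inflammation, smooth muscle, primitive globins, erythroid cells, yolk sac endoderm, endothelium, cell cycle, ribosomal proteins, glycolysis and hypoxia, steroid synthesis and metabolism, cholesterol synthesis, extracellular matrix, oxidative phosphorylation, interferon response, complement and coagulation, vasoactive and angiogenic factors, and Y-linked genes. They were tested in the 8 comparisons other than the steps with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Tests of each list between tissues at single stages were added after the data were seen.

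Genes named were the 8 with the largest positive and the 8 with the largest negative difference among called genes with the same sign in every probe set, the 3 called members with the largest difference in each called list, and the Y-linked and primitive globin genes. The text gives a selection of these, made after the values were seen, and leaves out genes whose call ended without 1 library, apart from Clec4n and the 5 genes called from e13.5 to e15.0 in placenta. Members against their list outside this rule were not refitted under the alternatives. Members that go against their list, values of the named genes in single steps, and the genes of steps with 5 or fewer calls were read after the data were seen.

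The gene test was tested on simulated data with 200 changed genes among 18193 in each comparison. In the comparison of tissues 97, 100 and 100% of genes changed by 1.5-fold, 2-fold and 4-fold were recovered, and in placenta from e19.0 to P0 these shares were 20.9, 79.1 and 97%. Alternatives were quantile normalization, centring on array medians, the mean over a gene's probe sets, leaving out genes below the 40th percentile, array weights, a trended and robust spread, only the compared groups, only the first technical array, other stages in the contrasts, replicate numbers as a block and leaving out each sample in turn. A pseudocount of 1, the 3' to 5' difference of the Gapdh control probe sets as a covariate, and fits or list tests without doubted placenta e9.0 samples were added after the data were seen.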

Results

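Expression of 18193 genes was measured in 40 samples of mouse placenta and decidua on 42 arrays. Dissected placenta came from e8.5 (1 sample), e9.0, e10.5, e12.0, e15.0 and e17.0 (3 each), and e13.5, e19.0 and the day of birth, P0 (2 each). Dissected decidua came from e8.5, e9.0, e10.5, e12.0, e15.0, e17.0, e19.0 and P0, with 2 samples at each stage, and undissected placenta with decidua from e17.0 (2 samples). Per the labels, replicates of dissected tissue were pools from separate litters, while both undissected samples came from 1 female of another strain. Median intensities of the arrays lay between 156.7 and 190.9. Differences are on the log2(value + 16) scale, which understates changes of dim genes, and are given with the standard error of the fit. The number of arrays limits the precision.

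The first component of the principal component analysis held 44.8% of the variance and the second 23.1%. Tdo2, a tryptophan-degrading enzyme of decidual stroma, measured 11.97, 10.08 and 5.97 in placenta e9.0 replicates 1, 2 and 3, and the natural killer protease Gzma measured 11.38, 9.84 and 8.70. The difference between the 3' and 5' Gapdh control probe sets, a sign of RNA quality, ranged from -0.13 to 0.68 over the arrays and was highest in placenta e9.0 replicate 1.

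**Figure D1:**
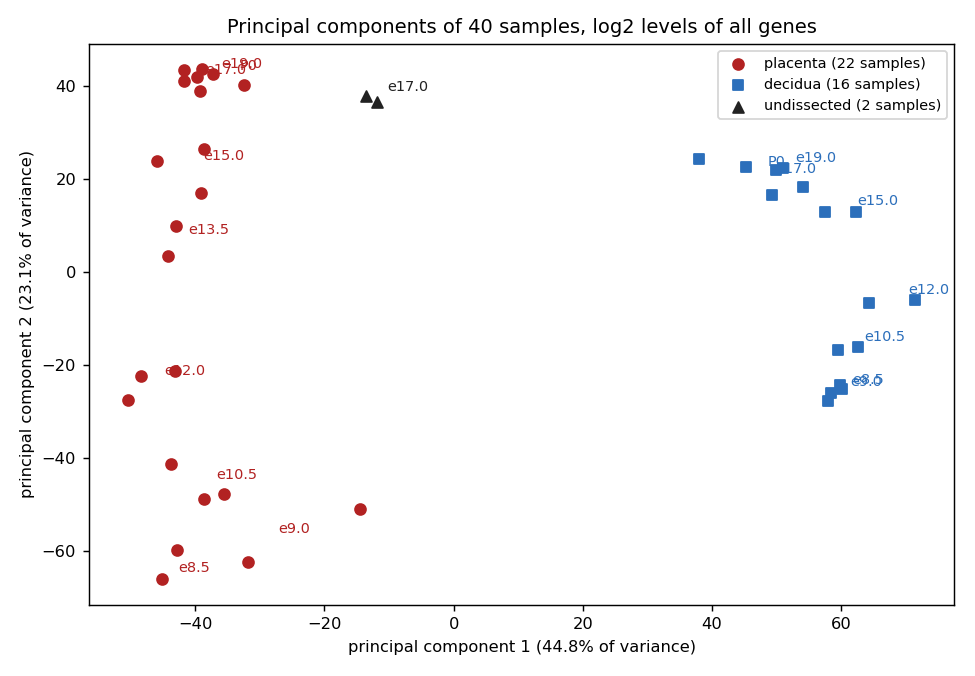
Scores of the 40 samples on the first component (44.8% of variance, horizontal axis) and the second component (23.1%, vertical axis) of log2 values, with 22 placental samples as circles, 16 decidual samples as squares and 2 undissected samples as triangles. Each point is 1 sample, and placenta e9.0 replicate 1 lies away from the other placenta e9.0 samples.

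Placenta and decidua were dissected apart, and the first comparison asked which genes differ between them over 7 shared stages (19 placental and 14 decidual samples). Car4, a carbonic anhydrase, had a mean of 7.26 in decidua and 12.48 in placenta, a difference of 5.22 ± 0.15 (adjusted p = 2.93e-21). Gjb2, the connexin of the labyrinth's syncytiotrophoblast, was higher in placenta by 4.61 ± 0.13, and Fabp3, a fatty acid binding protein, by 4.33 ± 0.12. In the other direction, Shisa3 had a mean of 11.55 in decidua and 6.11 in placenta (-5.44 ± 0.14, adjusted p = 4.2e-22). The water channel Aqp1 differed by -5.31 ± 0.18. In all, 10640 genes were called, 5522 higher in placenta and 5118 higher in decidua, of which 968 and 961 differed by at least 2-fold. For 63 of 83 named genes, chosen by the difference, all 19 placental samples lay on its side of their stage's decidual mean (fewest 13). Each list below was also tested at each stage, after the data were seen and adjusted over 203 tests. Of the 24 lists called over all stages, 5 were called at all 7 (labyrinth, imprinted genes, decidual stroma, macrophages and extracellular matrix). Another 14 kept their sign by the test but missed the call at some stages, and 5 turned. Of the 14, cathepsins and the PSG and CEACAM family were not called at e9.0 and e10.5, nor transporters up to e12.0. Prolactin, spongiotrophoblast (mean 0.05 at e17.0, adjusted p = 0.777) and vasoactive lists were not called from e17.0 on, natural killer cells from e19.0, interferon response from e15.0, and yolk sac and primitive globins (median -0.25 at P0) from e12.0. Erythroid genes were called at e10.5 and e12.0 alone, neutrophils not at e9.0, e15.0 or e17.0, giant cells not at e10.5 and complement not at e15.0. With an estimated correlation, labyrinth held at 6 stages, from e10.5 on, and no other list that kept its sign held at any.

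Lists of placental hormones, proteases and layers were higher in placenta. Of 15 prolactin family members, 12 were higher and 3 lower, and 15 passed when adjusted over the list alone (median 1.12, adjusted p = 0.00145, adjusted p = 0.24 with an estimated correlation). Prl2b1 was higher by 2.77 ± 0.18, against Prl7b1 (-1.15 ± 0.17), Prl7c1 (-0.44) and Prl4a1 (-0.29). In the PSG and CEACAM family, secreted pregnancy glycoproteins and their relatives, 12 of 13 were higher, 0 lower and 1 not called, with 13 adjusted over the list alone (median 1.37, adjusted p = 3.56e-05, adjusted p = 0.167 with an estimated correlation). Psg17 differed by 2.45 ± 0.14 and Psg18 by 2.32 ± 0.17. Placental cathepsins, lysosomal proteases of trophoblast, were higher in 6 of 8, lower in 1 (Cts8, -0.39 ± 0.06) and not called in 1, with 7 adjusted over the list alone (median 2.37, adjusted p = 0.003, adjusted p = 0.167 with an estimated correlation).

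Labyrinth and syncytiotrophoblast markers were higher in 8 of 10, lower in 1 (the transcription factor Cebpa, -0.75 ± 0.06) and not called in 1, with 9 adjusted over the list alone. Esx1 differed by 3.70 ± 0.10 and Pparg by 2.89 ± 0.11, and of the lists called in the comparison of tissues this alone held with an estimated correlation (median 1.91, adjusted p = 8.99e-05, and 0.0445 estimated). Spongiotrophoblast and glycogen cell markers were higher in 8 of 9, lower in 0 and not called in 1, with 9 adjusted over the list alone (median 0.87, adjusted p = 0.000466, adjusted p = 0.14 with an estimated correlation). Phlda2, an imprinted brake on placental growth, was higher by 3.33 ± 0.11. Trophoblast giant cell markers were higher in 6 of 10, lower in 3 (Bhlhe40, -1.51 ± 0.07, Lifr and Serpinb9b) and not called in 1, with 10 adjusted over the list alone (median 1.74, adjusted p = 0.0204, adjusted p = 0.254 with an estimated correlation). Hand1, a factor that giant cells need, differed by 3.11 ± 0.10.

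Nutrient transporters were higher in 13 of 22, lower in 5 and not called in 4, with 19 adjusted over the list alone (median 0.45, adjusted p = 0.00769, adjusted p = 0.256 with an estimated correlation). Slc38a4, an amino acid transporter, differed by 3.41 ± 0.15 and the iron exporter Slc40a1 by 2.82 ± 0.10, against Slc6a6 (-1.80 ± 0.09), Slc2a3, Slc23a2, Slc7a8 and Slco2a1. Among imprinted genes 22 of 32 were higher, 7 lower and 3 not called, with 30 adjusted over the list alone (median 0.78, adjusted p = 0.000119, adjusted p = 0.14 with an estimated correlation). Dlk1 was higher by 4.04 ± 0.12 and Meg3 by 3.47 ± 0.15. Gatm (-4.94 ± 0.25), Tfpi2 (-4.90 ± 0.21), Dcn, Osbpl5, Cd81, Impact and Tssc4 were lower. Cell cycle genes were higher in 25 of 29, lower in 2, the ribonucleotide reductase genes Rrm1 (-1.87 ± 0.07) and Rrm2 (-2.65 ± 0.11), and not called in 2, with 27 adjusted over the list alone. Ccne2 differed by 1.96 ± 0.09 (list median 0.92, adjusted p = 2.32e-07, adjusted p = 0.14 with an estimated correlation). The list was called higher in placenta at the earlier stages only, with mean differences of 1.47 at e9.0, 1.76 at e10.5, 1.95 at e12.0 (adjusted p = 0.0442, 0.0285 and 0.0285 with an estimated correlation) and 0.47 at e15.0 (adjusted p = 0.000121, adjusted p = 0.204 with an estimated correlation). At e17.0, e19.0 and P0 the means were -0.21, -0.31 and -0.34 (adjusted p = 0.54, 0.065 and 0.0522).

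Lists of blood and yolk sac were also higher in placenta. All 3 primitive globins, the embryonic forms of haemoglobin, were higher, with 3 adjusted over the list alone (median 1.49, adjusted p = 0.0235, adjusted p = 0.254 with an estimated correlation). Erythroid genes were higher in 9 of 16, lower in 1 (Sptb, -0.24 ± 0.05) and not called in 6, with 10 adjusted over the list alone (median 0.26, adjusted p = 0.0464, adjusted p = 0.31 with an estimated correlation). Yolk sac endoderm genes were higher in 17 of 23, lower in 3 (the retinol carrier Rbp4, -1.96 ± 0.18, Apoc2 and Hnf4a) and not called in 3, with 20 adjusted over the list alone (median 0.50, adjusted p = 0.00341, adjusted p = 0.31 with an estimated correlation). Afp, a secreted fetal serum protein, differed by 3.35 ± 0.44. Oxidative phosphorylation genes were higher in 16 of 26, lower in 2 (Sdhb, -1.14 ± 0.07, and Ndufa1) and not called in 8, with 18 adjusted over the list alone (median 0.22, adjusted p = 0.0464, adjusted p = 0.563 with an estimated correlation). By stage this list was called at e10.5, e12.0 and e15.0 (means 0.53, 0.68 and 0.26, adjusted p = 0.36, 0.256 and 0.534 with an estimated correlation). At e17.0, e19.0 and P0 its means were -0.19, -0.10 and -0.13 (adjusted p = 0.262, 0.439 and 0.284).

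Decidual stroma markers were lower in placenta in 19 of 22, higher in 1 (the phosphatase Alpl, 2.40 ± 0.11) and not called in 2, with 20 adjusted over the list alone (median -3.01, adjusted p = 1.12e-09, adjusted p = 0.14 with an estimated correlation). Sfrp4, a Wnt inhibitor, differed by -4.62 ± 0.14 and the muscle filament gene Des by -4.34 ± 0.11. Uterine natural killer cell markers were lower in 14 of 19, higher in 0 and not called in 5, with 14 adjusted over the list alone (median -1.23, adjusted p = 1.65e-05, adjusted p = 0.146 with an estimated correlation). Among them were the granzymes Gzmc (-2.93 ± 0.16) and Gzmg (-2.67 ± 0.19). Macrophage and leukocyte markers were lower in 17 of 20, higher in 2 (Adgre1, 0.39 ± 0.07, and Csf1r, 0.17 ± 0.07) and not called in 1, with 19 adjusted over the list alone (median -1.85, adjusted p = 3.7e-08, adjusted p = 0.14 with an estimated correlation). Fcer1g differed by -3.82 ± 0.15 and the lysosomal marker Cd68 by -3.01 ± 0.09. Neutrophil and acute inflammation genes were lower in 13 of 22, higher in 1 (Cxcr2, 1.56 ± 0.08) and not called in 8, with 14 adjusted over the list alone (median -0.29, adjusted p = 0.00527, adjusted p = 0.167 with an estimated correlation).

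Extracellular matrix genes were lower in placenta in 18 of 27, higher in 6 (Fbln1, 0.66 ± 0.16, Fn1, Col1a1, Col5a1, Col6a2 and Eln) and not called in 3, with 24 adjusted over the list alone (median -0.56, adjusted p = 0.000112, adjusted p = 0.152 with an estimated correlation). Interferon response genes were lower in 16 of 22, higher in 2 (Rsad2, 0.79 ± 0.10, and Oas2) and not called in 4, with 18 adjusted over the list alone (median -0.45, adjusted p = 0.000512, adjusted p = 0.162 with an estimated correlation). Complement and coagulation genes were lower in 13 of 19, higher in 5 (Tfpi, 0.76 ± 0.04, Thbd, Plat, F5 and Anxa5) and not called in 1, with 18 adjusted over the list alone (median -0.53, adjusted p = 0.003, adjusted p = 0.14 with an estimated correlation). Serping1, the inhibitor of complement C1, differed by -3.89 ± 0.19. Vasoactive and angiogenic factors were lower in 13 of 23, higher in 6 (Aplnr, 1.76 ± 0.11, Agtr1a, Flt1, Hif1a, Ptgis and Angpt1) and not called in 4, with 19 adjusted over the list alone (median -0.24, adjusted p = 0.0364, adjusted p = 0.24 with an estimated correlation).

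Glycolysis and hypoxia genes were lower in 12 of 21, higher in 2 (P4ha2, 0.98 ± 0.11, and Pdk1) and not called in 7, with 14 adjusted over the list alone (median -0.13, adjusted p = 0.00743, adjusted p = 0.24 with an estimated correlation). Egln3, an oxygen-sensing hydroxylase, differed by -2.30 ± 0.09, in this direction in 13 of 19 placental samples. At e9.0 it was higher in placenta (1.33 ± 0.22, adjusted p = 1.89e-05), as was Adm, a member of this and the vasoactive list (2.05 ± 0.38), and from e12.0 on it was lower. The list means were 0.29 at e9.0 and 0.05 at e10.5 (adjusted p = 0.174 and 0.494), and from -0.88 to -0.58 at the 5 later stages, each called (adjusted p = 0.134 to 0.391 with an estimated correlation). Cholesterol synthesis genes were lower in 7 of 14, higher in 1 (Fdft1, 0.65 ± 0.09) and not called in 6, with 8 adjusted over the list alone (median -0.23, adjusted p = 0.0464, adjusted p = 0.317 with an estimated correlation). Ribosomal protein genes were lower in 21 of 46, higher in 6 (Rps4l, 2.75 ± 0.13, Rpl12, Rpl14, Rps25, Rpl4 and Rpl6) and not called in 19, with 27 adjusted over the list alone (median -0.12, adjusted p = 0.0468, adjusted p = 0.612 with an estimated correlation). Their mean turned to 0.04 under quantile normalization (adjusted p = 0.856). By stage they were called lower at e17.0 (mean -0.59) and e19.0 (-0.17, adjusted p = 0.218 and 0.676 with an estimated correlation). At e9.0, e10.5 and e12.0 the means were 0.18, 0.15 and 0.13 (adjusted p = 0.596, 0.381 and 0.652). Cholesterol genes turned at e10.5 alone (mean 0.01, adjusted p = 0.781). Of the Y-linked genes, which only male fetuses carry, Eif2s3y differed by 2.04 ± 0.20 (adjusted p = 5.07e-10), Kdm5d by 0.12 ± 0.05 (adjusted p = 0.0486) and Uty by 0.17 ± 0.08 (adjusted p = 0.0595). All 3 members passed when adjusted over the list alone, and the list with its median of 0.17 was not called (adjusted p = 0.178).

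Another 4 lists were not called between tissues. Trophoblast stem and progenitor cell markers were higher in 4, lower in 4 and not called in 4, with 8 adjusted over the list alone (adjusted p = 0.89). Endothelial markers were higher in 7, lower in 10 and not called in 3, with 17 adjusted over the list alone (adjusted p = 0.397), an average over opposite stages. They were lower in placenta at e9.0, e10.5 and e12.0 (list medians -1.02, -0.97 and -0.83, adjusted p = 0.044, 0.1 and 0.139 with an estimated correlation). They were higher at e17.0, e19.0 and P0 (0.61, 0.72 and 0.43, adjusted p = 0.218, 0.197 and 0.325 with an estimated correlation). Steroid synthesis and metabolism genes were higher in 6, lower in 5 and not called in 2, with 11 adjusted over the list alone (adjusted p = 0.531). Smooth muscle genes were higher in 6, lower in 4 and not called in 3, with 10 adjusted over the list alone (adjusted p = 0.526), and their median (0.15) and mean (-0.14) differed in sign. Several calls ended under another setting. Without dim genes, these were the giant cell (adjusted p = 0.0653), neutrophil (0.0715), primitive globin (0.0645), erythroid (0.224), yolk sac (0.204), cholesterol (0.0589) and oxidative phosphorylation (0.189) lists. With arrays centred on their medians these were the erythroid (0.0506), ribosomal (0.0731) and oxidative phosphorylation (0.0562) lists. The ribosomal call also ended without placenta e9.0 replicate 1 (adjusted p = 0.0572), the erythroid call under quantile normalization (0.0811), and with the mean over a gene's probe sets the erythroid (0.0641), ribosomal (0.0616) and oxidative phosphorylation (0.059) calls. With replicate 3 alone standing for placenta e9.0, the erythroid (0.0539), ribosomal (0.0788) and cholesterol (0.055) calls ended. One named gene, Apob of the yolk sac list, turned from 1.49 ± 0.25 to -0.13 with a pseudocount of 1.

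**Figure D2:**
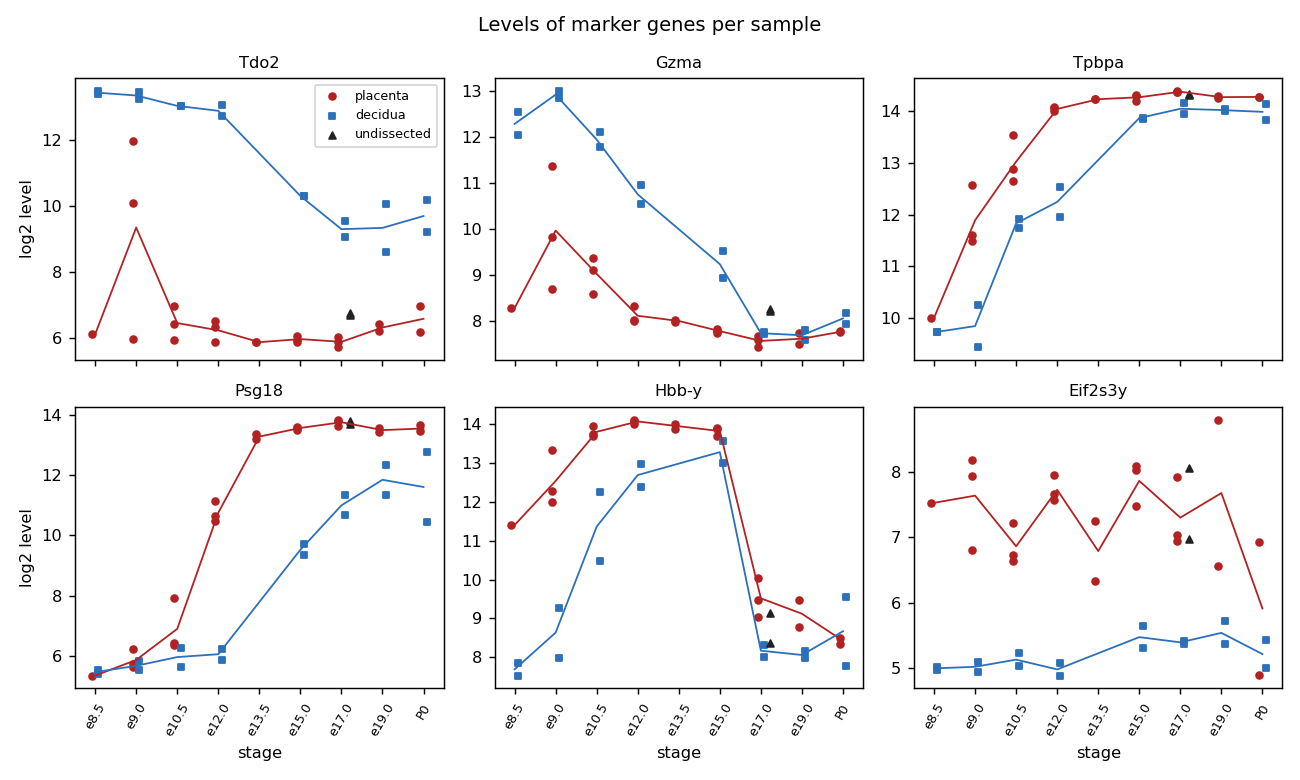
Log2 values (vertical axis) of 6 genes in each of the 40 samples by stage (horizontal axis), with placenta, decidua and undissected tissue drawn apart. Each point is 1 sample, and Tdo2 in placenta e9.0 measured 11.97, 10.08 and 5.97 in replicates 1, 2 and 3.

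The time course in placenta set late gestation (e15.0, e17.0 and e19.0, 8 samples) against e9.0 and e10.5 (6 samples). Psg18, a secreted pregnancy glycoprotein, rose from 6.38 to 13.61, by 7.23 ± 0.26 (adjusted p = 2.52e-18), Ceacam14 rose by 7.87 ± 0.50, the cathepsin Cts6 by 7.60 ± 0.42 and the prolactin family hormone Prl8a8 by 6.88 ± 0.31. Star, the mitochondrial cholesterol carrier that starts steroid synthesis, fell from 13.03 to 8.60 (-4.44 ± 0.14, adjusted p = 5.87e-19). Hsd3b3, a steroid dehydrogenase, fell too (-4.08 ± 0.14). The embryonic globin Hbb-bh1 had the largest decrease of all named genes (-5.15 ± 0.31). In all, 8607 genes were called, 3916 up and 4691 down, of which 987 and 898 changed by at least 2-fold. All 8 late samples lay on the side of the change from the early mean for 48 of the 50 genes named for it. The exceptions were Hbb-y (5 of 8) and Slc7a8 (7 of 8).

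Cell cycle genes fell in 28 of 29 and rose in 0, with 1 not called and 29 adjusted over the list alone (median -2.22, adjusted p = 7.07e-25, and 0.00315 with an estimated correlation). Cdc6 and Mcm5, which license replication origins, fell (-3.88 ± 0.13 and -4.04 ± 0.16), as did Birc5 (-3.77 ± 0.14). Nutrient transporters rose in 17 of 22, fell in 2 (Slc2a3, -1.67 ± 0.16, and Slc39a8, -0.53 ± 0.16) and were not called in 3, with 19 adjusted over the list alone (median 1.33, adjusted p = 1.25e-09, and 0.0405 estimated). The iron exporter Slc40a1 rose by 2.97 ± 0.15 and the prostaglandin transporter Slco2a1 by 2.16 ± 0.12. Interferon response genes rose in 16 of 22 and fell in 0, with 6 not called and 18 adjusted over the list alone (median 0.70, adjusted p = 1.76e-08, and 0.0405 estimated). Usp18 rose by 2.48 ± 0.16 and Oasl2 by 2.32 ± 0.16. These 3 lists were the ones that held with an estimated correlation in this comparison.

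The PSG and CEACAM family rose in 11 of 13, fell in 1 (Ceacam9, -4.30 ± 0.21) and was not called in 1, with 12 adjusted over the list alone (median 5.43, adjusted p = 1.21e-10, adjusted p = 0.05 with an estimated correlation). Prolactin family members rose in 9 of 15, fell in 4 (Prl4a1, -3.43 ± 0.18, Prl6a1, Prl7a1 and Prl7c1) and were not called in 2, with 13 adjusted over the list alone (median 1.34, adjusted p = 0.00692, adjusted p = 0.352 with an estimated correlation). Placental cathepsins rose in 6 of 8 and fell in 2 (Cts7, -3.44 ± 0.17, and Cts8), with 8 adjusted over the list alone (median 4.72, adjusted p = 0.000291, adjusted p = 0.117 with an estimated correlation). Labyrinth and syncytiotrophoblast markers rose in 7 of 10 and fell in 0, with 3 not called and 8 adjusted over the list alone (median 0.96, adjusted p = 0.00143, adjusted p = 0.05 with an estimated correlation). Pparg, a lipid-sensing nuclear receptor, rose by 1.94 ± 0.17. Extracellular matrix genes rose in 17 of 27, fell in 2 (Timp1, -1.27 ± 0.09, and Mmp11) and were not called in 8, with 21 adjusted over the list alone (median 0.62, adjusted p = 3e-06, adjusted p = 0.102 with an estimated correlation). Complement and coagulation genes rose in 7 of 19, fell in 2 (Procr, -1.42 ± 0.14, and Thbd) and were not called in 10, with 9 adjusted over the list alone (median 0.29, adjusted p = 0.0315, adjusted p = 0.236 with an estimated correlation).

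Primitive globins fell in 3 of 3, with 3 adjusted over the list alone (median -2.35, adjusted p = 0.00248, adjusted p = 0.161 with an estimated correlation). Ribosomal protein genes fell in 39 of 46 and rose in 0, with 7 not called and 40 adjusted over the list alone (median -0.46, adjusted p = 3.64e-10, adjusted p = 0.228 with an estimated correlation). Oxidative phosphorylation genes fell in 22 of 26 and rose in 0, with 4 not called and 23 adjusted over the list alone (median -0.58, adjusted p = 3.45e-07, adjusted p = 0.181 with an estimated correlation). Cholesterol synthesis genes fell in 11 of 14, rose in 1 (Fdft1, 0.51 ± 0.14) and were not called in 2, with 12 adjusted over the list alone (median -0.72, adjusted p = 0.000215, adjusted p = 0.117 with an estimated correlation). Yolk sac endoderm genes fell in 11 of 23, rose in 3 (Sox17, 0.71 ± 0.12, Gata6 and Alb) and were not called in 9, with 15 adjusted over the list alone (median -0.38, adjusted p = 0.027, adjusted p = 0.486 with an estimated correlation). Uterine natural killer cell markers fell in 12 of 19 and rose in 0, with 7 not called and 12 adjusted over the list alone (median -0.54, adjusted p = 0.00143, adjusted p = 0.248 with an estimated correlation). Gzmd fell (-3.13 ± 0.32), and the same cell type's Gzma had stood at 11.38, 9.84 and 8.70 in placenta e9.0 replicates 1, 2 and 3.

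The remaining 14 lists were not called in placenta, among them steroid synthesis and metabolism (adjusted p = 0.0751), macrophages and leukocytes (0.0808), endothelium (0.0827), trophoblast giant cells (0.0967) and imprinted genes (0.103). With replicate 3 alone standing for placenta e9.0, 7544 genes were called. The yolk sac call ended without placenta e9.0 replicate 1 (adjusted p = 0.0546) and without dim genes (0.434), and that of complement and coagulation under quantile normalization (0.0592) and without dim genes (0.186).

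In decidua the same stages were compared (6 late and 4 early samples). Ceacam14 rose from 5.40 to 11.55, by 6.16 ± 0.59 (adjusted p = 4.23e-09), Psg21 by 5.75 ± 0.49, the hormone Prl8a6 by 5.63 ± 0.37 and the retinol carrier Rbp4 from 7.34 to 12.61, by 5.28 ± 0.33. Gzma, a protease of natural killer cells, fell from 12.44 to 8.23 (-4.20 ± 0.27, adjusted p = 1.69e-12), as did Bmp2, a growth factor of decidualization (-4.48 ± 0.29), the endothelial lipase Lipg (-4.89 ± 0.27) and the metallothionein Mt4 (-5.46 ± 0.37). In all, 4356 genes were called, 2287 up and 2069 down (2633 and 1613 with centred arrays), of which 513 and 324 changed by at least 2-fold. All 6 late samples lay on the side of the change from the early mean for 63 of the 65 genes named for it. Exceptions were C1qa and C1qb (5 of 6 each).

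Spongiotrophoblast and glycogen cell markers rose in 6 of 9 and fell in 0 in decidua, with 3 not called and 7 adjusted over the list alone (median 2.19, adjusted p = 1.5e-07, and 0.0194 with an estimated correlation). Tpbpb rose by 4.62 ± 0.21 and Tpbpa, the standard marker of this layer, by 3.15 ± 0.17. The PSG and CEACAM family rose in 11 of 13 and fell in 2 (Ceacam9, -2.48 ± 0.25, and Ceacam15), with 13 adjusted over the list alone (median 4.98, adjusted p = 1.83e-13, and 0.0206 estimated). Glycolysis and hypoxia genes rose in 16 of 21 and fell in 0, with 5 not called and 16 adjusted over the list alone (median 0.88, adjusted p = 1.83e-13, and 0.00395 estimated). Egln3 rose from 7.79 to 11.61, by 3.82 ± 0.16 (adjusted p = 2.42e-16), and Ankrd37 by 2.25 ± 0.13. Uterine natural killer cell markers fell in 13 of 19 and rose in 0, with 6 not called and 13 adjusted over the list alone (median -1.70, adjusted p = 1.03e-11, and 0.0206 estimated). The pore protein Prf1 fell (-3.79 ± 0.26). Endothelial markers fell in 16 of 20, rose in 2 (Kdr, 0.98 ± 0.27, and Cdh5, 0.50 ± 0.08) and were not called in 2, with 18 adjusted over the list alone (median -1.12, adjusted p = 2.83e-13, and 0.00353 estimated). Emcn fell (-2.74 ± 0.14), and so did Plvap (-2.20 ± 0.14).

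Cell cycle genes fell in decidua in 18 of 29 and rose in 0, with 11 not called and 22 adjusted over the list alone (median -0.53, adjusted p = 1.15e-10, and 0.0295 with an estimated correlation). Steroid synthesis and metabolism genes fell in 5 of 13, rose in 2 (Cyp17a1, 1.13 ± 0.29, and Hsd17b11) and were not called in 6, with 8 adjusted over the list alone (median -0.36, adjusted p = 0.00547, and 0.0241 estimated). Akr1c18, which breaks down progesterone, fell (-3.02 ± 0.29), and so did Star (-2.05 ± 0.17). These 7 lists were the ones that held with an estimated correlation in decidua.

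Prolactin family members rose in 10 of 15, fell in 4 (Prl6a1, -3.84 ± 0.18, Prl7a1, Prl4a1 and Prl5a1) and were not called in 1, with 14 adjusted over the list alone (median 2.80, adjusted p = 5.91e-06, adjusted p = 0.125 with an estimated correlation). Placental cathepsins rose in 6 of 8 and fell in 2 (Cts7, -3.33 ± 0.20, and Cts8), with 8 adjusted over the list alone (median 2.17, adjusted p = 0.00244, adjusted p = 0.189 with an estimated correlation). Giant cell markers rose in 6 of 10, fell in 1 (Hand1, -0.63 ± 0.18) and were not called in 3, with 7 adjusted over the list alone (median 0.71, adjusted p = 0.0335, adjusted p = 0.319 with an estimated correlation). Nutrient transporters rose in 7 of 22, fell in 4 (Slc39a8, -0.93 ± 0.19, Slc1a5, Abcg2 and Slc23a2) and were not called in 11, with 12 adjusted over the list alone (median 0.19, adjusted p = 0.00499, adjusted p = 0.293 with an estimated correlation). Imprinted genes rose in 12 of 32, fell in 4 (Mest, -2.26 ± 0.18, Grb10, Plagl1 and Ppp1r9a) and were not called in 16, with 18 adjusted over the list alone (median 0.15, adjusted p = 0.00893, adjusted p = 0.293 with an estimated correlation). The growth factor Igf2 rose by 3.52 ± 0.18.

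Macrophage and leukocyte markers rose in 10 of 20, fell in 4 (Ptprc and the antigen presentation genes Cd74, -0.98 ± 0.17, H2-Aa and H2-Ab1) and were not called in 6, with 14 adjusted over the list alone (median 0.43, adjusted p = 0.00243, adjusted p = 0.319 with an estimated correlation). Lysozyme Lyz2 rose by 2.87 ± 0.30. Extracellular matrix genes rose in 16 of 27, fell in 5 (Bgn, -2.72 ± 0.19, Postn, Timp1, Col6a2 and Col1a1) and were not called in 6, with 21 adjusted over the list alone (median 0.49, adjusted p = 0.000937, adjusted p = 0.211 with an estimated correlation). Lumican, Lum, rose by 4.81 ± 0.27. Complement and coagulation genes rose in 7 of 19, fell in 1 (C1ra, -0.62 ± 0.12) and were not called in 11, with 8 adjusted over the list alone (median 0.17, adjusted p = 0.00432, adjusted p = 0.125 with an estimated correlation). Decidual stroma markers fell in 9 of 22, rose in 2 (Cebpb, 0.64 ± 0.10, and Rxfp1) and were not called in 11, with 11 adjusted over the list alone (median -0.33, adjusted p = 0.000937, adjusted p = 0.319 with an estimated correlation).

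Cholesterol synthesis genes fell in 9 of 14 and rose in 0, with 5 not called and 10 adjusted over the list alone (median -0.59, adjusted p = 6.28e-05, adjusted p = 0.0769 with an estimated correlation). Oxidative phosphorylation genes fell in 9 of 26 and rose in 0, with 17 not called and 10 adjusted over the list alone (median -0.32, adjusted p = 9.37e-05, adjusted p = 0.293 with an estimated correlation). Ribosomal protein genes fell in 8 of 46, rose in 1 (Rps4l, 1.01 ± 0.23) and were not called in 37, with 7 adjusted over the list alone (median -0.19, adjusted p = 0.00156, adjusted p = 0.533 with an estimated correlation). Labyrinth and syncytiotrophoblast markers were not called as a list (2 rose, 0 fell, 8 not called, adjusted p = 0.372), nor were the other 9 lists. The giant cell call ended under quantile normalization (adjusted p = 0.106), centring (0.0518) and without dim genes (0.105).

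**Figure D3:**
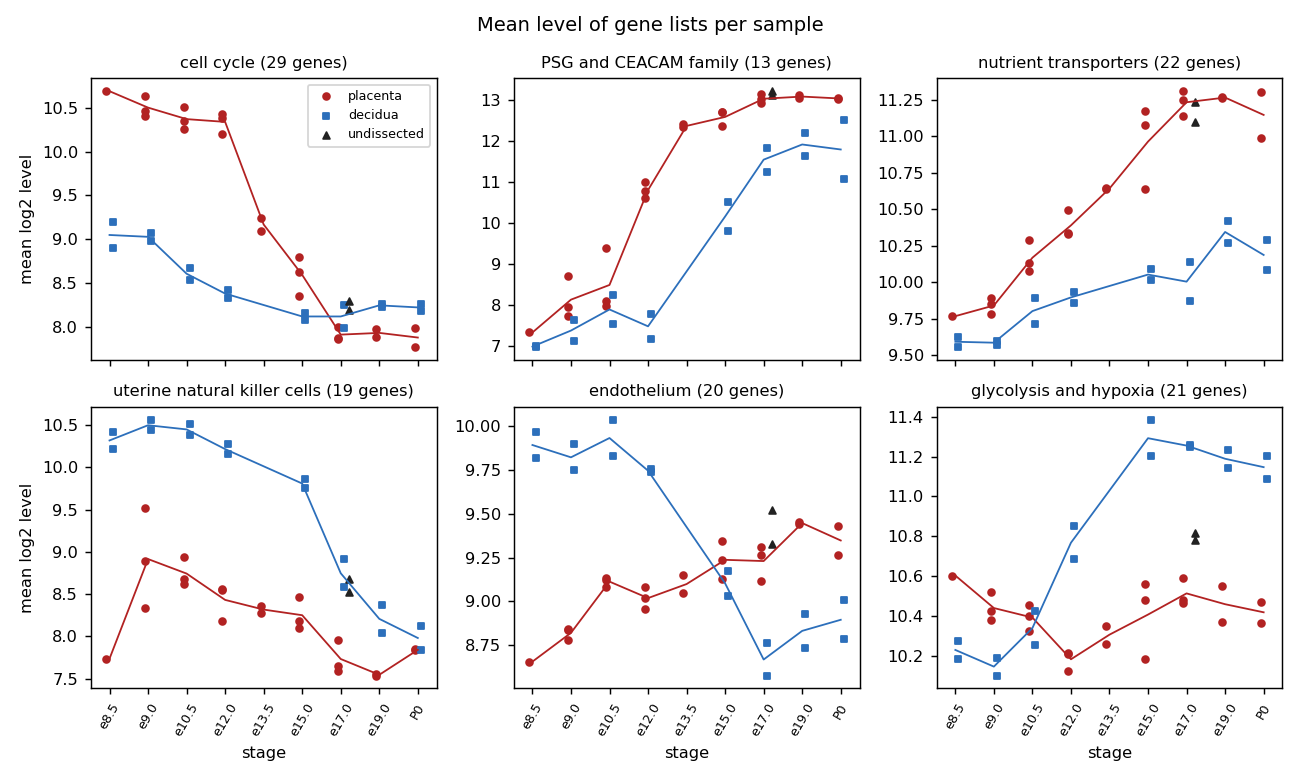
Mean log2 value (vertical axis) of the measured members of 6 gene lists by stage (horizontal axis), with a point per sample and a line through the means of placenta or decidua. Among the lists shown, the 29 cell cycle genes had a median change of -2.22 from early to late in placenta and -0.53 in decidua.

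The change from early to late was then compared between tissues (24 samples), as placental less decidual change. Plvap, a protein of fenestrated endothelium, differed by 4.25 ± 0.18 (adjusted p = 2.93e-15), the leptin receptor Lepr by 4.66 ± 0.24 and Prl3c1 by 7.52 ± 0.58. Rbp4 differed by -7.71 ± 0.43 (adjusted p = 2.78e-13), Egln3 by -4.88 ± 0.20 and the angiogenic factor Pgf by -4.59 ± 0.32. The test of the difference called 6115 genes, 2785 toward placenta and 3330 toward decidua, of which 967 and 1096 differed by at least 2-fold. Genes called in both tissues overlapped as well: 1141 rose in both (492.3 if the calls were independent), 831 fell in both (533.5) and 683 moved in opposite directions.

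Endothelial markers moved toward placenta in 15 of 20, toward decidua in 2 (Flt4, -0.49 ± 0.17, and Cdh5, -0.45 ± 0.11) and were not called in 3, with 17 adjusted over the list alone (median 1.10, adjusted p = 6.39e-10, and 0.00804 with an estimated correlation). Emcn differed by 3.40 ± 0.18 and Tek, the angiopoietin receptor, by 2.78 ± 0.19. Cell cycle genes moved toward decidua in 28 of 29 and toward placenta in 0, with 1 not called and 28 adjusted over the list alone (median -1.57, adjusted p = 2.08e-20, and 0.00804 estimated), Cdc6 by -3.12 ± 0.21. These 2 lists held with an estimated correlation in the test of the difference.

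Cathepsins moved toward placenta in 5 of 8, toward decidua in 0 and were not called in 3, with 5 adjusted over the list alone (median 2.45, adjusted p = 0.00196, adjusted p = 0.231 with an estimated correlation). For the PSG and CEACAM family these numbers were 8, 1 (Ceacam9, -1.82 ± 0.32) and 4 of 13, with 10 adjusted over the list alone (median 1.34, adjusted p = 0.0109, adjusted p = 0.566 with an estimated correlation). For nutrient transporters they were 13, 2 (Slc2a3, -1.79 ± 0.25, and Slc2a1) and 7 of 22, with 16 adjusted over the list alone (median 0.57, adjusted p = 8.94e-05, adjusted p = 0.207 with an estimated correlation). Interferon response genes had 12, 1 (Mx1, -0.41 ± 0.16) and 9 of 22, with 14 adjusted over the list alone (median 0.69, adjusted p = 3.62e-06, adjusted p = 0.108 with an estimated correlation). Natural killer cell markers had 6, 2 (Gzmd, -1.41 ± 0.50, and Itgae) and 11 of 19, with 8 adjusted over the list alone (median 0.24, adjusted p = 0.0128, adjusted p = 0.566 with an estimated correlation).

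Spongiotrophoblast and glycogen cell markers moved toward decidua in 7 of 9, toward placenta in 1 (Egfr, 1.13 ± 0.20) and were not called in 1, with 8 adjusted over the list alone (median -1.47, adjusted p = 0.00144, adjusted p = 0.197 with an estimated correlation). Glycolysis and hypoxia genes moved toward decidua in 13 of 21, toward placenta in 1 (Ndrg1, 0.69 ± 0.15) and were not called in 7, with 15 adjusted over the list alone (median -0.69, adjusted p = 1.8e-05, adjusted p = 0.108 with an estimated correlation). Primitive globins had 3 of 3 toward decidua and 3 adjusted over the list alone (median -2.19, adjusted p = 0.0128, adjusted p = 0.323 with an estimated correlation). Yolk sac endoderm genes had 12 of 23 toward decidua, 2 (Sox17, 2.65 ± 0.19, and Alb) toward placenta and 9 not called, with 16 adjusted over the list alone (median -0.56, adjusted p = 0.00447, adjusted p = 0.566 with an estimated correlation). Ribosomal protein genes had 18 of 46 toward decidua, 0 toward placenta and 28 not called, with 19 adjusted over the list alone (median -0.35, adjusted p = 7.41e-05, adjusted p = 0.583 with an estimated correlation). Oxidative phosphorylation genes had 10 of 26 toward decidua, 1 (Ndufa4, 0.94 ± 0.21) toward placenta and 15 not called, with 11 adjusted over the list alone (median -0.38, adjusted p = 0.0297, adjusted p = 0.652 with an estimated correlation).

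Calls of the difference that ended under another setting were those of the natural killer cell (adjusted p = 0.0621) and yolk sac (0.325) lists without dim genes and of primitive globins with the mean over probe sets (0.0519). The call of oxidative phosphorylation ended under quantile normalization (0.0833), without dim genes (0.0942) and with the mean over probe sets (0.0663). For the list of steroid synthesis and metabolism, which was not called, the median (0.23) and the mean (-0.18) differed in sign.

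Steps between adjacent stages showed when the placental changes took place. From e10.5 to e12.0 Psg18 rose by 3.86 ± 0.39 (adjusted p = 4.36e-07) and Ctsm by 4.28 ± 0.41. Hsd3b3 (-2.89 ± 0.22) and Star (-2.26 ± 0.21) fell. From e12.0 to e13.5 Cts6 rose by 5.63 ± 0.70 and Prl8a8 by 5.34 ± 0.52 (adjusted p = 4.57e-07). Cdc6 (-1.74 ± 0.22) and Ceacam9 (-2.89 ± 0.35) fell. From e15.0 to e17.0 the embryonic globins Hbb-y (-4.30 ± 0.41, adjusted p = 2.56e-07) and Hba-x (-2.14 ± 0.33) fell.

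In decidua, 27 of the 65 genes named for early to late change rose and 9 fell over the longest step, e12.0 to e15.0. Psg21 rose by 5.08 ± 0.76 (adjusted p = 0.000128), Prl8a6 by 4.46 ± 0.58 and Tpbpb by 3.18 ± 0.32. The progesterone-degrading Akr1c18 (-3.19 ± 0.45) and the keratinocyte envelope gene Sprr2h (-3.44 ± 0.46) fell. Bmp2 (-2.80 ± 0.44), Aplnr (-2.23 ± 0.30) and Star (-2.06 ± 0.26) fell from e10.5 to e12.0.

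Over all genes, placental steps called 1012 genes from e9.0 to e10.5 (412 up, 600 down), 592 from e10.5 to e12.0 (372 up, 220 down) and 720 from e12.0 to e13.5 (172 up, 548 down). Later placental steps called 5 genes from e13.5 to e15.0, 460 from e15.0 to e17.0 (212 up, 248 down) and 40 from e17.0 to e19.0 (32 up, 8 down). The 5 genes, named after their values were seen, were Phlda2 (-1.85 ± 0.28), Prl6a1 (-1.67 ± 0.25), Cdk1 (-0.94 ± 0.15), Scel (1.31 ± 0.22) and Itpka (1.15 ± 0.15), and each lost its call under some alternatives. The direction of the first step turned with the scaling: with arrays centred on their medians 685 rose and 199 fell, and under quantile normalization 831 rose and 387 fell. Quantile normalization gave 446 up and 442 down from e10.5 to e12.0, 306 and 514 from e12.0 to e13.5, 11 and 9 from e13.5 to e15.0, and 36 and 19 from e17.0 to e19.0. Centring gave 150 and 273 from e15.0 to e17.0.

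Array weights gave 7792, 4206, 777 and 201 genes in the placental steps from e9.0, e10.5, e15.0 and e17.0. With only the compared groups these steps called 2, 282, 49 and 2, with 1109 from e12.0 and 0 from e13.5. The Gapdh covariate, added after the data were seen, gave 527 from e9.0 and 13 from e13.5, and 18 were called from e17.0 without dim genes.

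The first placental step also depended on single libraries, with 362, 378 and 1937 genes without placenta e9.0 replicate 1, 2 or 3, and 234, 434 and 1593 without e10.5 replicate 1, 2 or 3. Using replicate 3 alone for e9.0 left 68. From e10.5 to e12.0 the count was 166, 174 or 1598 without e10.5 replicate 1, 2 or 3, and 149 or 242 without e12.0 replicate 1 or 2. Leaving out e12.0 replicate 1 or 3 gave 410 or 358 genes from e12.0 to e13.5, and leaving out e13.5 replicate 1 or 2 gave 342 or 280. Between e13.5 and e15.0 it was 25 or 1 without e13.5 replicate 1 or 2, and 20 or 18 without e15.0 replicate 2 or 3. Between e15.0 and e17.0 it was 300 or 277 without e15.0 replicate 1 or 3, and 216 or 163 without e17.0 replicate 2 or 3. From e17.0 to e19.0 it was 90, 23 or 20 without e17.0 replicate 1, 2 or 3, and 5 or 21 without e19.0 replicate 1 or 2.

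Decidual steps called 0 genes from e8.5 to e9.0 by limma (584 at an unadjusted p below 0.05), 117 from e9.0 to e10.5 (69 up, 48 down), and 239 from e10.5 to e12.0 (121 up, 118 down, against 103 and 148 under quantile normalization and 103 and 117 with centred arrays). Later steps called 392 from e12.0 to e15.0 (250 up, 142 down), 95 from e15.0 to e17.0 (38 up, 57 down, against 69 up and 42 down under quantile normalization) and 62 from e17.0 to e19.0 (42 up, 20 down). Leaving out 1 library gave 3 or 1 without e8.5 replicate 1 or 2 in the first of these steps. In the step to e10.5 it gave 46 or 38 without e9.0 replicate 1 or 2 and 35 or 72 without e10.5 replicate 1 or 2, and in the step to e12.0 94 without e10.5 replicate 2 and 55 or 153 without e12.0 replicate 1 or 2. In the step to e15.0 it gave 202 or 182 without e12.0 replicate 1 or 2 and 166 without e15.0 replicate 2. In the step to e17.0 it gave 36 without e15.0 replicate 2 and 15 without e17.0 replicate 1, and in the last 38 or 11 without e17.0 replicate 1 or 2 and 10 without e19.0 replicate 1. Array weights gave 6, 316 and 569 genes in the decidual steps from e8.5, e9.0 and e10.5, and only the compared groups 41, 134, 112, 1 and 0 in those from e9.0, e10.5, e12.0, e15.0 and e17.0.

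**Figure D4:**
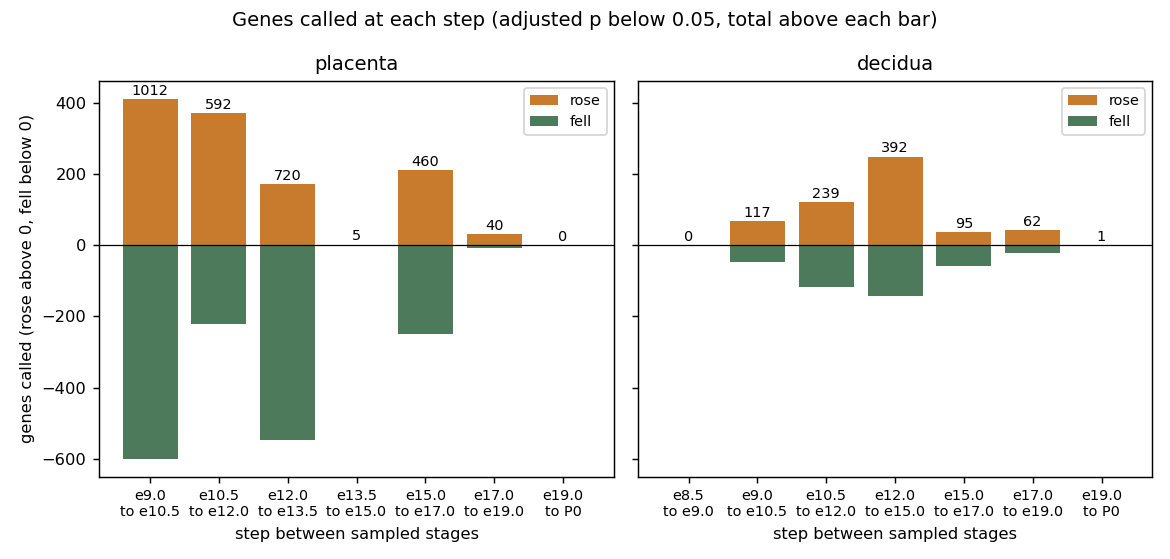
Number of called genes (vertical axis) at each step between adjacent stages (horizontal axis) in placenta and decidua, with bars above 0 for genes that rose and below 0 for genes that fell. The tallest total is 1012 genes from e9.0 to e10.5 in placenta, whose split into 412 up and 600 down turned to 685 and 199 with arrays centred on their medians.

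Around birth, P0 was compared with e19.0 (2 samples at each stage and tissue). Clec4n, a lectin receptor of macrophages, fell in decidua from 9.15 to 8.11 (-1.04 ± 0.17, adjusted p = 0.0229, lower in 2 of 2 samples) and was the 1 gene called there (308 at an unadjusted p below 0.05). Its call ended without decidua e19.0 replicate 1 (-0.92) and without P0 replicate 1 (-0.90), with array weights and with only the compared groups. Without decidua e19.0 replicate 2, P0 replicate 1 or P0 replicate 2, 6, 8 or 57 genes were called in decidua. In placenta limma called 0 genes (392 at an unadjusted p below 0.05, smallest adjusted p = 0.756). It called 1 without e19.0 replicate 2 and 16 without P0 replicate 1.

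Small shifts over whole lists were called around birth, with 0 single members called over all genes. Where no other number is given, 0 members passed when adjusted over the list alone. In placenta, ribosomal proteins shifted up (median 0.10, adjusted p = 0.000359, adjusted p = 0.784 with an estimated correlation), as did natural killer cell markers (median 0.14, adjusted p = 0.00131, adjusted p = 0.671 with an estimated correlation). Labyrinth markers shifted down (median -0.18, adjusted p = 0.00131, adjusted p = 0.113 with an estimated correlation), with 2 of 10 members adjusted over the list alone, and so did cholesterol synthesis (median -0.23, adjusted p = 0.0148, adjusted p = 0.671 with an estimated correlation). In decidua, the prolactin family shifted up (median 0.15, adjusted p = 0.000693, adjusted p = 0.866 with an estimated correlation), with 2 of 15 adjusted over the list alone. Macrophage markers (median -0.24, adjusted p = 0.00228, adjusted p = 0.866 with an estimated correlation) and nutrient transporters (median -0.17, adjusted p = 0.0196, adjusted p = 0.866 with an estimated correlation, 1 of 22 adjusted over the list alone) shifted down. The ribosomal call ended under quantile normalization (adjusted p = 0.102), the cholesterol call with the mean over probe sets (0.0857) and the decidual transporter call under both (0.0698 and 0.27).

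Undissected e17.0 tissue (2 samples, 1 dam) was compared with dissected placenta (3 samples) and decidua (2) of that stage. Against placenta, Tfpi2, a protease inhibitor, was higher by 4.82 ± 0.54 (8.47 in placenta, 13.30 undissected, adjusted p = 8.4e-07), Gatm by 4.77 ± 0.64 and Aqp1 by 4.39 ± 0.46. Against decidua, Car4 was higher by 5.63 ± 0.43 (from a decidual mean of 7.37, adjusted p = 1.77e-10) and Gjb2 by 5.03 ± 0.36, while the chitinase-like Chil3 (-4.61 ± 0.34) and arginase Arg1 (-4.36 ± 0.35) were lower. Both undissected samples lay on the side of the difference for all 31 named genes against placenta and 49 against decidua. Strain, pooling and dissection also differed, and p-values leave out variation between dams.

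Against placenta 3271 genes were called, 2762 higher and 509 lower (555 and 93 by at least 2-fold), and the median of all genes lay at 0.10. Decidual stroma markers were higher in 13 of 22, lower in 0 and not called in 9, with 14 adjusted over the list alone (median 1.27, adjusted p = 1.38e-05, adjusted p = 0.815 with an estimated correlation). Natural killer cell markers were higher in 7 of 19, lower in 0 and not called in 12, with 10 adjusted over the list alone (median 0.48, adjusted p = 0.0151, adjusted p = 0.922 with an estimated correlation). Macrophage and leukocyte markers were higher in 5 of 20, lower in 0 and not called in 15, with 11 adjusted over the list alone (median 0.55, adjusted p = 0.0245, adjusted p = 0.922 with an estimated correlation). Extracellular matrix genes were higher in 9 of 27, lower in 0 and not called in 18, with 11 adjusted over the list alone (median 0.43, adjusted p = 0.003, adjusted p = 0.815 with an estimated correlation). Ribosomal protein genes were higher in 25 of 46, lower in 0 and not called in 21, with 30 adjusted over the list alone (median 0.43, adjusted p = 1.53e-06, adjusted p = 0.922 with an estimated correlation). The split became 1291 higher and 1168 lower with arrays centred on their medians, and 1753 and 1381 under quantile normalization. Without placenta e17.0 replicate 2 or 3 the count was 1887 or 1890, without undissected replicate 1 or 2 it was 1012 or 1433, without dim genes 1965 and with array weights 6969.

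Against decidua 4970 genes were called, 3421 higher and 1549 lower (1012 and 646 by at least 2-fold), with the median of all genes at 0.11. Labyrinth and syncytiotrophoblast markers were higher in 7 of 10, lower in 1 (Cebpa, -0.85 ± 0.16) and not called in 2, with 8 adjusted over the list alone (median 1.73, adjusted p = 2.22e-05, and 0.0151 with an estimated correlation, which this list alone passed). The PSG and CEACAM family was higher in 7 of 13, lower in 0 and not called in 6, with 8 adjusted over the list alone (median 1.54, adjusted p = 0.00149, adjusted p = 0.386 with an estimated correlation). Cathepsins were higher in 6 of 8, lower in 0 and not called in 2, with 6 adjusted over the list alone (median 2.30, adjusted p = 0.0031, adjusted p = 0.278 with an estimated correlation). Giant cell markers were higher in 5 of 10, lower in 1 (Bhlhe40, -1.13 ± 0.19) and not called in 4, with 6 adjusted over the list alone (median 1.52, adjusted p = 0.0177, adjusted p = 0.366 with an estimated correlation). Nutrient transporters were higher in 12 of 22, lower in 2 (Slc6a6, -1.13 ± 0.25, and Slc23a2) and not called in 8, with 16 adjusted over the list alone (median 0.71, adjusted p = 0.000167, adjusted p = 0.204 with an estimated correlation). Imprinted genes were higher in 18 of 32, lower in 3 (Osbpl5, -2.08 ± 0.21, Cd81 and Ascl2) and not called in 11, with 21 adjusted over the list alone (median 0.65, adjusted p = 0.000571, adjusted p = 0.204 with an estimated correlation). Endothelial markers were higher in 11 of 20, lower in 1 (Cdh5, -0.52 ± 0.13) and not called in 8, with 12 adjusted over the list alone (median 0.79, adjusted p = 0.00149, adjusted p = 0.204 with an estimated correlation).

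Macrophage and leukocyte markers were lower in undissected tissue than in decidua in 11 of 20, higher in 0 and not called in 9, with 16 adjusted over the list alone (median -0.94, adjusted p = 6.68e-07, adjusted p = 0.204 with an estimated correlation). Decidual stroma markers were lower in 10 of 22, higher in 3 (Prl3c1, 2.45 ± 0.68, Alpl and Wnt6) and not called in 9, with 14 adjusted over the list alone (median -0.88, adjusted p = 0.00155, adjusted p = 0.448 with an estimated correlation). Glycolysis and hypoxia genes were lower in 9 of 21, higher in 2 (Car9, 0.82 ± 0.15, and Pdk1) and not called in 10, with 12 adjusted over the list alone (median -0.41, adjusted p = 0.000418, adjusted p = 0.204 with an estimated correlation). Ribosomal protein genes were lower in 5 of 46, higher in 0 and not called in 41, with 1 adjusted over the list alone (median -0.11, adjusted p = 0.00387, adjusted p = 0.626 with an estimated correlation). Complement and coagulation genes were lower in 5 of 19, higher in 2 (Plat, 0.61 ± 0.17, and Anxa5) and not called in 12, with 8 adjusted over the list alone (median -0.03, adjusted p = 0.033, adjusted p = 0.314 with an estimated correlation). Under quantile normalization that call ended (adjusted p = 0.0624). The split of all genes was 2133 higher and 2418 lower with centred arrays, and 2552 and 2413 under quantile normalization. Without decidua e17.0 replicate 2 the count was 2808 and without undissected replicate 1 it was 2780.

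Genes outside both dissected tissues numbered 1345, of which 1287 were higher than both and 58 lower than both (172 and 11 by at least 2-fold). Against the nearer tissue, Noct, a clock-regulated gene, was higher by 3.05 ± 0.16 (adjusted p = 3.39e-13), and Pttg1, the securin of dividing cells, by 2.41 ± 0.24. Lower were Cap1, an actin regulator (-2.08 ± 0.21, adjusted p = 1.92e-07), the transcription factor Sall1 (-1.17 ± 0.24) and Rab3gap1 (-1.04 ± 0.22). With independent calls 519.4 genes would be higher than both and 43.3 lower. Simulated samples with no effect gave 0, with independent noise and no shift of whole arrays. Both comparisons share the undissected samples, so part of the excess may come from them. The split was 573 higher and 205 lower with centred arrays, and 754 and 228 under quantile normalization. The count was 857 or 876 without placenta e17.0 replicate 2 or 3, 616 without decidua e17.0 replicate 2, 372 or 676 without undissected replicate 1 or 2, 693 without dim genes and 2434 with array weights.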

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

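Among the tests given here, those on the rise of trophoblast genes in decidua were chosen only after the result was seen. The change from early to late gestation differed between placenta and decidua by a test of the difference itself for 6115 genes. Of 100 reassignments of tissue labels within stages, the highest other gave 3223 genes. They also break the tissue difference, so cannot test the change alone. Chance is argued against between tissues (10640 genes, highest other 6782) and from early to late in placenta (8607, 5338) and decidua (4356, 2288). In each, 1 of 100 splits was as large, the real one. Of the 10 splits of 6 samples, too few for a share under 0.05, 2 reached the 1012 genes from e9.0 to e10.5 in placenta (highest other 1116, the exchange of both replicate 3 samples). From e10.5 to e12.0 the real split gave 592 and the highest other 0, and from e15.0 to e17.0 460 and 111.

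Of the gene lists called by the same test at the preset correlation, endothelium (median difference 1.10, toward placenta) and cell cycle (-1.57, toward decidua) held with an estimated correlation (adjusted p = 0.00804 each). Lists that did not hold, with their p from the estimated correlation, were toward placenta cathepsins (2.45, adjusted p = 0.231), the PSG and CEACAM family (1.34, adjusted p = 0.566), interferon response (0.69, adjusted p = 0.108), nutrient transporters (0.57, adjusted p = 0.207) and natural killer cells (0.24, adjusted p = 0.566). Toward decidua they were primitive globins (-2.19, adjusted p = 0.323), spongiotrophoblast and glycogen cells (-1.47, adjusted p = 0.197), glycolysis and hypoxia (-0.69, adjusted p = 0.108), yolk sac endoderm (-0.56, adjusted p = 0.566), oxidative phosphorylation (-0.38, adjusted p = 0.652) and ribosomal proteins (-0.35, adjusted p = 0.583). Natural killer cell, primitive globin, yolk sac and oxidative phosphorylation calls also ended under another setting.

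Single genes with a placental change above the decidual one were Prl3c1 (7.52), the endothelial lipase Lipg (5.05), Tent5a (5.02), the leptin receptor Lepr (4.66), the proteoglycan Bgn (4.46), Cavin2 (4.32), Plvap (4.25) and the peptidase Mme (4.24). Genes with a decidual change above the placental one were Rbp4 (-7.71), Prl7c1 (-4.89), Egln3 (-4.88), Bex1 (-4.85), the matrix protease Mmp11 (-4.59), Pgf (-4.59), the protease Klk4 (-4.35) and the estrogen sulfotransferase Sult1e1 (-3.95).

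Trophoblast genes rose in decidua from early to late, by a median of 4.98 over the PSG and CEACAM family and 2.19 over spongiotrophoblast and glycogen cell markers. For the former, array scaling alone is argued against (mean at least 3.51 with arrays centred or quantile normalized). Carry-over of placental tissue of every layer was weighed against 9 labyrinth and transporter members, whose implied placental shares had a median of 0.029 (quartiles 0.001 and 0.119) but reached 0.506 in Slc16a3 and 0.134 in Pparg. By exact two-sided permutation of genes (not independent), PSG and CEACAM members argue against it (median share 0.278, adjusted p = 0.014). So do 4 spongiotrophoblast members (0.574, adjusted p = 0.014) and, narrowly, prolactins (0.214, 0.041 to 1.278, above any share, adjusted p = 0.0354). For 6 cathepsins it stays open (0.08, 0.041 to 0.178, adjusted p = 0.433). An untested signal ceiling would raise shares (Tpbpa, 14.2 to 14.39 in late placenta). Fetal cells stay open, as Y-linked Eif2s3y changed by 0.39 ± 0.36 (spread shared with placenta, adjusted p = 0.488, 95% interval -0.34 to 1.13). Decidua held 4.94 to 5.23 early and 5.30 to 5.71 late. The median share of 0.223 over 26 PSG and CEACAM, prolactin and cathepsin members would give 1.07. Spongiotrophoblast left on the decidua or trophoblast that invaded it may explain the rise, which no test separates.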

How the results depend on the processing

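The pseudocount of 1, the Gapdh covariate and the fits without doubted placenta e9.0 samples were chosen only after the results were seen. Of the counts of called genes, 314 stayed within 1.5 times under an alternative and 98 did not; those between tissues, from early to late and of the difference stayed within it under all that were run. Of the named genes' alternatives 12387 kept direction and call, 355 lost the call (256 without 1 library, 64 with only the compared groups) and 1 reversed: Apob between tissues, -0.13 with a pseudocount of 1. Of 95 list calls 14 held with an estimated correlation and 81 did not; calls were lost by 13 lists without dim genes, 8 under quantile normalization, 7 with the mean over probe sets, 4 with centred arrays, 3 with placenta e9.0 from 1 sample and 2 without placenta e9.0 replicate 1. Fits with 1 sample in an arm assume that it varies like the other groups. Where a value moved and nothing below says why, the cause was not tested. Signal near the background limits dim genes, since log2(value + 16) compresses their changes. With placenta e9.0 from 1 sample, 10721 genes were called between tissues, 7544 from early to late in placenta and 6197 for the difference.

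Leaving out 1 library gave 10304 to 10804 genes between tissues, 7844 to 8676 and 3314 to 4386 from early to late in placenta and decidua, and 5375 to 6401 for the difference. Ranges for undissected tissue were 1012 to 3457 against placenta, 2780 to 3957 against decidua and 372 to 1375 outside both. In placental steps they were 234 to 1937 (e9.0 to e10.5), 149 to 1598 (e10.5 to e12.0), 280 to 675 (e12.0 to e13.5), 1 to 25 (e13.5 to e15.0), 163 to 584 (e15.0 to e17.0), 5 to 90 (e17.0 to e19.0) and 0 to 16 (e19.0 to P0). In decidual steps they were 0 to 3 (e8.5 to e9.0), 35 to 72 (e9.0 to e10.5), 55 to 161 (e10.5 to e12.0), 166 to 407 (e12.0 to e15.0), 15 to 102 (e15.0 to e17.0), 10 to 53 (e17.0 to e19.0) and 1 to 57 (e19.0 to P0).

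Array weights, which ran from 0.307 (placenta e9.0 replicate 1) to 8.01 (placenta e10.5 replicate 2), gave 7792, 4206, 777 and 201 genes in the placental steps from e9.0, e10.5, e15.0 and e17.0, 6, 316, 569 and 0 in the decidual steps from e8.5, e9.0, e10.5 and e19.0, 6969 against dissected placenta and 2434 outside both. With only the compared groups, which leaves fewer degrees of freedom, placental steps called 2 (from e9.0), 282 (e10.5), 1109 (e12.0), 0 (e13.5), 49 (e15.0) and 2 (e17.0) genes, and decidual steps 41 (e9.0), 134 (e10.5), 112 (e12.0), 1 (e15.0), 0 (e17.0) and 0 (e19.0). Without dim genes, where fewer genes are tested, 18 were called from e17.0 to e19.0 in placenta, 0 from e19.0 to P0 in decidua, 1965 against dissected placenta and 693 outside both. Centred arrays gave 778 outside both. From e13.5 to e15.0 in placenta, 20 were called under quantile normalization, 11 with a trended and robust spread, 8 with the first technical array and 13 with the Gapdh covariate. The Gapdh covariate gave 527, and placenta e9.0 from 1 sample 68, from e9.0 to e10.5 in placenta; the Gapdh difference itself was called for 2909 genes as a term.

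Replicate numbers were tried as a block, although no label says they mark shared litters. Of 14 same-stage pairs of placenta and decidua with 1 number, 13 had deviations that correlated above 0.1 (mean 0.338, lowest 0.002 at e10.5, highest 0.573). The rule that every pair exceed 0.1 was not met. Pairs with different numbers averaged -0.197 (2 of 24 above 0.1), but deviations mirror each other in groups of 2. Equal numbers across stages averaged 0.165 between and 0.158 within tissues, hinting at a factor beyond litter that unblocked counts and reassigned labels leave out. Replicate 1 exceeded replicate 2 in the Gapdh difference at every shared stage and tissue. With the block 1683 genes were called from e9.0 to e10.5, 1168 from e12.0 to e13.5 and 101 from e13.5 to e15.0 in placenta. Other counts moved by less than 1.5 times, such as 11161 between tissues, 9401 and 4983 early to late in placenta and decidua, and 6808 for the difference.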

Other observations

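Of the tests in this part, those on the shape of placental change at mid-gestation, on scaling, strain and genes outside a mix in undissected tissue, on decidual tissue in placenta e9.0 and on exchanged labels were chosen only after the result was seen. Some placental genes peaked or dipped at mid-gestation (e12.0 and e13.5 against both early and late stages): 140 peaked and 118 dipped by limma, 3 of each by at least 2-fold both ways. Hsd11b2, which inactivates glucocorticoids, stood 1.40 ± 0.16 above early and 2.09 ± 0.15 above late gestation, the hormone Prl7b1 1.77 ± 0.30 and 1.58 ± 0.28, and the pericyte gene Rgs5 1.66 ± 0.26 and 1.21 ± 0.25. Adrenomedullin, Adm, dipped (-3.04 ± 0.25 and -1.13 ± 0.24), as did Ceacam15 (-2.41 ± 0.42 and -2.23 ± 0.40) and the protease Htra1 (-1.74 ± 0.28 and -1.22 ± 0.27). The single placenta e8.5 sample, with no replicate, held Star at 12.61, Hbb-bh1 at 12.99, Psg18 at 5.34 and Tdo2 at 6.10.

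Undissected e17.0 tissue had 1287 genes above both dissected tissues and 58 below both. Scaling as the whole cause is argued against, as 73.7% or more of the genes outside both stayed above under either other scaling. Simulated samples with no effect gave 0 genes in 50 draws. They held independent noise and no shift of whole arrays, so they do not bear on scaling. Strain, the single dam and dissection cannot be told apart, with 0 undissected samples of the other strain. At least 778 genes were outside both under each scaling (1345 as measured, against 447 between). Strain or dam could put them there, so a mix of both tissues in 1 proportion cannot be tested over all genes. For genes at least 8-fold apart it stays open as a hypothesis: 85 placenta-high genes gave a median placental share of 0.747 and 156 decidua-high genes 0.831, a difference of -0.085, with 0 of either outside both.

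Placenta e9.0 replicate 1 stood apart from its group. Decidual tissue in the sample is a candidate explanation: 39 of 41 stroma, natural killer and macrophage members implied a share above 0, with a median of 0.168 (quartiles 0.119 and 0.235). The members most abundant in decidua implied uneven shares, 0.425 for Srgn (13.88 in decidua), 0.274 for Gzmg (13.61) and 0.57, 0.238 and 0.235 for Gja1, Hand2 and Htra3 (13.55 each), and against replicate 3 alone replicate 2 gave a median of 0.051. RNA quality stays open, as the deviation correlated over genes, which are not independent, with the slope on the Gapdh difference at 0.473, between the bounds set for and against it. Exchanged replicate 3 labels of e9.0 and e10.5 are argued against, since on the axis from e8.5 to e12.0 the e10.5 sample lay 0.444 nearer to e12.0.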
